A study of Homo sapiens with 3 samples.

How the data were processed

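RNA-seq was available for 3 libraries of the TE5 esophageal squamous carcinoma line, 1 with a scrambled control and 2 with short hairpin RNA against KLF5, harvested after 48 h. Per the labels, total RNA was made into TruSeq libraries and sequenced on a HiSeq instrument. The authors deposited 1 table per library with the columns of a kallisto abundance table, and kallisto and DESeq2 are named, without versions, in the submitters' processing notes, as is the build hg19. The deposited estimated counts are kallisto's per-transcript counts, which need not be whole and are not normalised, per the file headers. The deposited TPM values are counts divided by effective length and scaled to the same sum in each library, per the file headers. The other deposited columns, length and effective length in bases, were used only to check the annotation and to build length-scaled counts, per the file headers. The transcript set, the kallisto index and the use of strand are not given in the sources used here. Kallisto divides reads shared by several transcripts among them, so values of paralogs and of overlapping genes are estimates, and library preparation without a stated strand leaves sense and antisense genes open to the same doubt.

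Each table listed 196354 transcripts, and 181857 of them (92.6%) were matched by Ensembl identifier to GENCODE 29, whose coordinates on GRCh38 are those printed. Of the matched transcripts 93.2% had the same length there. The 14497 unmatched transcripts held 3.05% of counts in scramble, 3.42% in shKLF5 library 1 and 3.40% in shKLF5 library 2 and were left out of gene totals. Estimated counts were summed per gene over 52992 genes and rounded to whole numbers. The group of each library came from the labels, and the labels' numbers 1 and 2 of the shKLF5 libraries were taken as members of 1 group.

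Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, estimateDisp, and the quasi-likelihood F test of shKLF5 (2 libraries) against scramble (1 library), run with legacy = FALSE, with Benjamini-Hochberg adjustment over 20629 genes and a threshold of 0.05. TMM factors were 0.82, 1.11 and 1.10 for scramble and shKLF5 libraries 1 and 2. There was 1 residual degree of freedom, the prior degrees of freedom were 6.86, and the common biological coefficient of variation was 32.9%. SE is the absolute log2 fold change divided by the square root of F, and intervals are at 95%. CPM are TMM-normalised unless stated otherwise, and SD is over the 2 shKLF5 libraries, since scramble has no replicate. Log2 fold changes of a single shKLF5 library used a prior count of 2 and carry no test. A fold against 0 counts was set to a floor of 3 counts in the scramble library. Intervals rest on the spread between the 2 shKLF5 libraries as well as on counting error, while the floor allows for counting error only. Reads carried no molecular identifiers, so counting error here is that of reads and not of molecules.

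Tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names KLF5, TP63, SOX2 and ALDH3A1, then 12 protein-coding genes each way. These are taken from genes called by the main test or, where fewer than 5 pass, from those with a mean CPM of at least 5 whose smaller fold change of the 2 libraries is largest, given as values and not as calls. It adds up to 4 members with the smallest p from each list. The 27 lists were the circuit factors, other KLF family members, other squamous transcription factors, basal squamous epithelium, squamous differentiation, stress keratins, epithelial junctions, mesenchymal genes, DNA replication, mitosis, p53 targets, interferon response, NF-kB, MAPK with AP-1, TGF-beta with YAP, NRF2 with aldehyde metabolism, hypoxia with glycolysis, cholesterol with fatty acid synthesis, unfolded protein with integrated stress response, ribosomal proteins, oxidative phosphorylation, mitochondrial mRNAs, replication-dependent histones, and markers of fibroblasts, leukocytes, endothelium and glandular epithelium. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the 27 lists, and again with an estimated correlation and with fry. With 1 degree of freedom the estimated correlation rests on almost no information. List medians were set beside those of 10000 random lists matched on mean expression in 20 bins. Agreement of the 2 libraries was compared with 100 simulations that had no effect and the same shared control.

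Alternatives were median-ratio size factors, library size alone, no filter on low counts, a mean CPM of at least 5, length-scaled TPM, edgeR's legacy fit, DESeq2 1.42.0, limma on log2(TPM + 1), a fold change limit, protein-coding genes, transcripts in place of genes, and each shKLF5 library left out in turn. DESeq2 ran on the rounded counts, and genes it gave no adjusted p stayed without one. A correction of each library for its trend with abundance by loess, and a fit without mitochondrially encoded genes, were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

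The test was run on simulated data before use. Counts were drawn for the 20629 genes of the shKLF5 against scramble comparison. Each gene was given the spread estimated for genes of its abundance, without scatter between genes of like abundance. Changes of 8-fold in 100 genes and 4-fold in 100 were planted among genes with a mean CPM of at least 5. Recovery may therefore be better than for the real genes. The edgeR test recovered 93% of the 8-fold genes and 44% of the 4-fold genes, with 8 false calls. A planted list of 30 genes shifted by -0.60 on the log2 scale had a camera adjusted p of 0.000272 with the preset correlation and 0.963 with an estimated correlation. The latter did not recover it in this design. The simulated genes were drawn independently, so the run cannot show whether the preset correlation holds for the real lists. Estimated correlations of those varied widely, such as 0.44 for the basal list, 0.772 for ribosomal proteins and -0.001 for mitosis.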

Results

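RNA was measured in TE5, a cell line from a human esophageal squamous cell carcinoma, with short hairpin RNA against KLF5 or with a scrambled control. KLF5 is a zinc finger transcription factor of proliferating epithelia. The series sets it beside TP63, the master factor of the basal squamous lineage, and SOX2, a factor of foregut progenitors, as members of a core regulatory circuit. There were 3 libraries from cells harvested after 48 h, 1 of the scramble group and 2 of the shKLF5 group, which the labels number 1 and 2 without saying whether they are separate hairpins or separate cultures. The p-values therefore measure the spread between these 2 libraries, which may be technical, and the single scramble library is assumed to vary as they do. The totals were 33448976 estimated counts in scramble, 33544752 in shKLF5 library 1 and 32720563 in shKLF5 library 2. Transcripts encoded in mitochondria took 31.4%, 26.9% and 30.9% of the counts as mRNA, in that order, and 6.66%, 4.13% and 3.80% as rRNA. At least 10 counts were found for 16920 genes in scramble, 19304 in shKLF5 library 1 and 19422 in shKLF5 library 2.

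The targeted gene was far lower in both shKLF5 libraries than in scramble. KLF5 (ENSG00000102554; GRCh38 chromosome 13, 73054976 to 73077542) had 8402 counts in scramble, 1333 in shKLF5 library 1 and 1531 in shKLF5 library 2, which is 316 CPM against 40.6 ± 4.83 CPM (SD, n = 2). The level was 8.48-fold lower in library 1 and 7.17-fold lower in library 2, and in TPM it was 182, 35.4 and 39.7. Both main coding transcripts of KLF5 were lower: KLF5-201 had 4160 counts in scramble against 620 and 691, and KLF5-205 had 3219 against 552 and 647. The log2 fold change was -2.96 (SE 0.34, 95% confidence interval -3.75 to -2.17). With edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.182 over the 20629 genes tested, and 7.95e-05 adjusted over the list alone, that of KLF5, TP63 and SOX2. DESeq2 gave an adjusted p of 1.51e-06 and edgeR's legacy fit 0.0149, and over the alternatives the adjusted p ran from 1.51e-06 to 0.611.

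The comparison also asks what became of the other circuit members when KLF5 was knocked down. TP63 was lower by value in both shKLF5 libraries. SOX2 was lower in library 2 and, after TMM scaling, near the scramble level in library 1. TP63 (ENSG00000073282; chromosome 3, 189631416 to 189897279) had 8380 counts in scramble, 4939 in library 1 and 2047 in library 2, or 315 CPM against 98.4 ± 55.8 CPM (SD, n = 2). Its log2 fold change was -1.68 (SE 0.49), with -1.19 in library 1 and -2.42 in library 2. SOX2 (ENSG00000181449; chromosome 3, 181711924 to 181714436) had 5899, 7876 and 2185 counts, or 222 CPM against 141 ± 111 CPM (SD, n = 2), and a log2 fold change of -0.65 (SE 0.62, 95% confidence interval -2.09 to 0.79). The SOX2 value against scramble was -0.01 in library 1 and -1.82 in library 2, a gap wider than its difference from scramble. By edgeR's quasi-likelihood test the adjusted p over all genes was 0.474 for TP63 and 0.756 for SOX2. Adjusted over the list alone, TP63 passed by edgeR's test and SOX2 did not. That list also holds KLF5, the target of the hairpins, whose low p eases the adjustment for TP63.

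**Figure D1:**
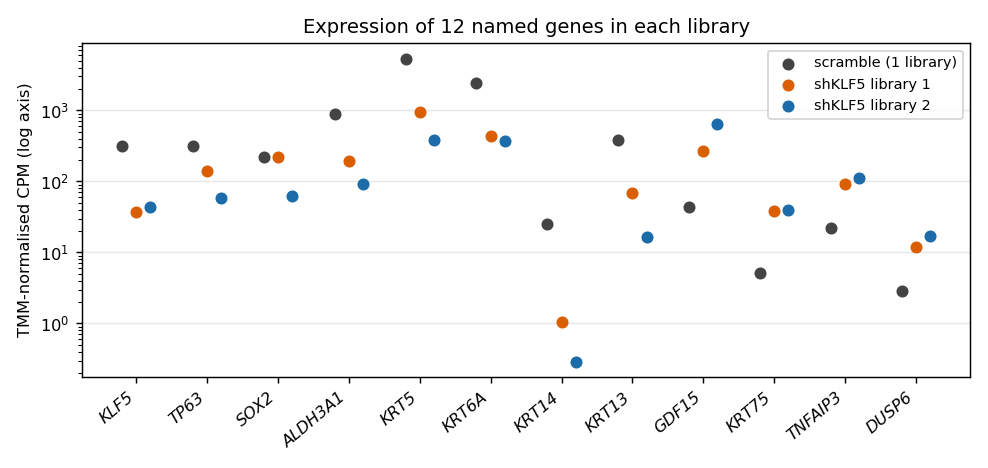
TMM-normalised CPM (log axis) of 12 named genes, 1 point per library, for scramble (n = 1) and the 2 shKLF5 libraries. KLF5 lies at 316 CPM in scramble and at 37.2 and 44.0 CPM in the shKLF5 libraries, and SOX2 at 222, 220 and 62.8 CPM.

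Among the 12 protein-coding genes picked by rule on each side, those lower in both shKLF5 libraries included the keratins KRT14, KRT5, KRT6A and KRT13 and the enzymes ADH7, CYP4F3, CYP4F12 and PRODH. Those higher in both included the secreted factors NTN1, GDF15 and IL32 and also the keratin KRT75. KRT14, the partner of KRT5 in basal cell filaments, had 659 counts in scramble against 37 and 10. KRT5 itself was abundant, with 142684 counts against 34119 and 13095, or 5367 CPM against 664 ± 407 CPM (SD, n = 2). KRT6A, a keratin of wounded and hyperproliferative epithelium, had 2411 CPM against 399 ± 43.1 CPM (SD, n = 2). KRT13, a keratin of esophageal suprabasal cells, had a log2 fold change of -3.18 (SE 0.68). Among enzymes, ADH7, the alcohol and retinol dehydrogenase of the upper digestive tract, stood at -3.62 (SE 0.48), CYP4F3 at -2.94 (SE 0.37), CYP4F12 at -4.10 (SE 0.57) and PRODH, which starts proline breakdown, at -3.26 (SE 0.51). UPK3B, PSAPL1 and MBOAT1 were also lower by value, with log2 fold changes of -4.57, -3.59 and -3.02. ALDH3A1 (ENSG00000108602; chromosome 17, 19737984 to 19748943), a detoxifying aldehyde dehydrogenase, had 23824, 7051 and 3174 counts and a log2 fold change of -2.64 (SE 0.47).

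On the other side, NTN1, which encodes the guidance cue netrin, had 0 counts in scramble against 405 and 372, at least 100.2-fold higher in library 1 and at least 94.8-fold higher in library 2 when the scramble library is set to a floor of 3 counts. GDF15, a stress-induced cytokine, had 1144 counts in scramble against 9545 and 22469, or 43.0 CPM against 456 ± 269 CPM (SD, n = 2). KRT75, a hair follicle keratin, had nearly equal levels in the 2 shKLF5 libraries, with 136 counts against 1351 and 1354 and a log2 fold change of 2.90 (SE 0.45). ABL2, a tyrosine kinase, stood at 2.73 (SE 0.47), PLA2G4C, a phospholipase, at 3.33 (SE 0.64), and IL32, an inflammatory cytokine, at 3.04 (SE 0.64). PMEPA1, a feedback inhibitor of TGF-beta signalling, had 15 counts in scramble against 173 and 347. RNASE7, an antimicrobial ribonuclease of epithelia, and TRAF1, an adaptor of TNF receptors, were higher by value with a wide gap between the libraries, RNASE7 with 16, 151 and 675 counts and TRAF1 with 37, 270 and 1194. The others picked by the same rule were BNC2 at 4.17, NEURL3 at 3.86 and ROBO4 at 3.64 on the log2 scale. In libraries 1 and 2 BNC2 stood at 2.91 and 4.64, NEURL3 at 2.67 and 4.33, and ROBO4 at 2.70 and 4.07.

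None of these named genes passed the main test over all genes. With edgeR's quasi-likelihood test 0 of 20629 genes reached a Benjamini-Hochberg adjusted p under 0.05, while 1893 had an unadjusted p under 0.05, 1171 of them higher and 722 lower. DESeq2 called 118 genes, 63 higher and 55 lower, and edgeR's legacy fit called 21, 5 higher and 16 lower, and all 21 were among those of DESeq2. The 21 included KLF5, KRT14, KRT5, KRT6A, ADH7, CYP4F3, CYP4F12, UPK3B and PRODH on the lower side and NTN1 and KRT75 on the higher side. The legacy calls also held genes with 0 counts in scramble or in both shKLF5 libraries, NTN1 among them. Others of this kind were the noncoding genes AL139099.1 (256, 0 and 0 counts), AL583722.2 (81, 0 and 0), AC006064.4 (0, 119 and 209) and LINC00115 (0, 101 and 119). Keratin paralogs and members of the CYP4F, AKR1C and histone families share sequence, so their single values are uncertain to the extent that estimated counts moved between copies.

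**Figure D2:**
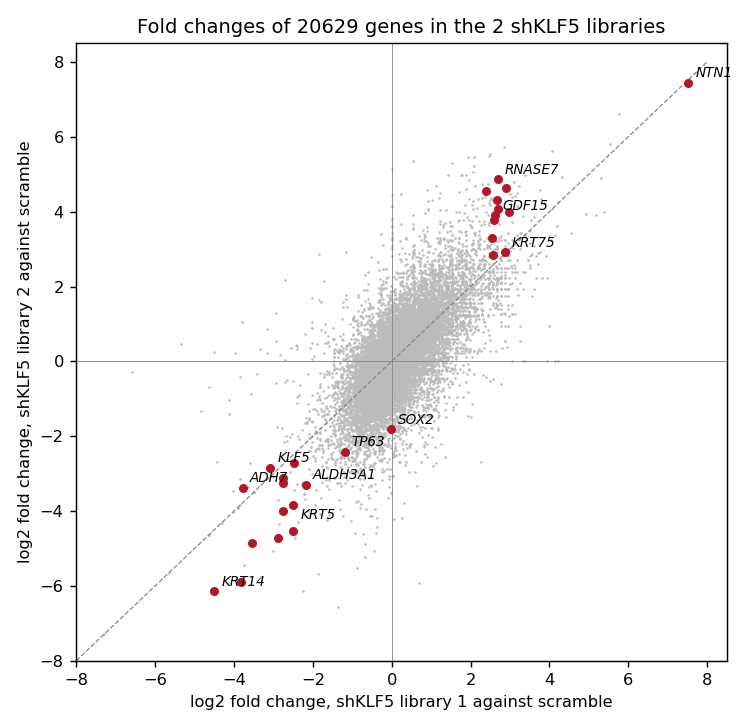
Log2 fold change against scramble of each of 20629 genes in shKLF5 library 1 (horizontal) and shKLF5 library 2 (vertical), computed with a prior count of 2 and with the genes named by rule in red. KLF5 lies at -3.08 and -2.84, TP63 at -1.19 and -2.42, and the dashed line marks equal values.

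Lists of squamous genes ranked lower in the shKLF5 libraries. Of 25 basal squamous genes, 22 were lower by value in both libraries, 2 were higher in both and 1 went opposite ways, with a median log2 fold change of -1.25. Besides the keratins these included DSG3, a desmosomal cadherin, at -1.55 (SE 0.36) and ITGA3, a laminin-binding integrin subunit, at -1.42 (SE 0.35). Of 5 stress keratins 4 were lower in both, with a median of -2.31, and KRT6A, KRT6C at -2.86, KRT16 at -2.31 (21, 6 and 5 counts) and KRT17 at -1.35, which the basal list also holds, passed when adjusted over the list alone. Of 24 differentiation and cornified envelope genes 15 were lower in both and 7 higher in both, with a median of -0.62: KRT4, a suprabasal keratin, had 70, 5 and 0 counts, KRT13 and EMP1 (-1.42) were lower, and FLG, the precursor of filaggrin, chosen after its values were seen, had 913, 3800 and 1948 counts. Camera with a preset correlation called these lists lower, with adjusted p = 1.42e-16 for the basal list, 2.24e-07 for stress keratins and 0.00361 for differentiation. The circuit list, with a median of -1.68, was also called by camera. But 1 of its 3 members is KLF5, the target of the hairpins, and SOX2 was near the scramble level in library 1 after TMM scaling. That call is therefore not counted with the squamous lists. Each of these had an adjusted p = 0.664 with an estimated correlation, so none of the calls held that way. Adjusted over the list alone, edgeR's test passed 8 of the basal genes, 4 of the stress keratins, 3 of the differentiation genes and 2 of the circuit, each of them lower. The median in libraries 1 and 2 was -0.73 and -1.65 for the basal list, -1.19 and -2.42 for the circuit and -0.39 and -0.61 for differentiation, whose call was lost among genes with a mean CPM of at least 5 (camera adjusted p = 0.0687).

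Lists of cell division genes also ranked lower. Of 37 DNA replication and G1/S genes 35 were lower by value in both shKLF5 libraries, with a median log2 fold change of -0.51, and of 38 mitotic genes 35 were lower in both, with a median of -0.54. MCM6, a subunit of the replicative helicase, stood at -1.26 (SE 0.35), TYMS, thymidylate synthase, at -1.09 (SE 0.35) and PCNA, the sliding clamp, at -1.04 (SE 0.38). CENPE, a kinetochore motor, stood at -1.64 (SE 0.34), TOP2A at -1.20 (SE 0.35) and MKI67, a proliferation marker, at -1.10 (SE 0.34). Camera with a preset correlation gave adjusted p = 1.57e-07 for the replication list and 1.40e-09 for the mitotic list, and both had an adjusted p = 0.664 with an estimated correlation. No single member of either list passed when adjusted over the list alone by edgeR's test. The medians were -0.57 and -0.54 for replication, and -0.69 and -0.52 for mitosis, in libraries 1 and 2. Over both libraries, the medians of -0.51 and -0.54 are to be read beside those of random lists of the same expression. These were -0.185 for replication and -0.197 for mitosis.

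Metabolic genes ranked lower as well, led by the targets of NRF2, the regulator of the response to oxidants. Of 33 NRF2 and aldehyde metabolism genes, 29 were lower by value in both libraries and 0 higher in both, with a median log2 fold change of -1.05, and 19 passed when adjusted over the list alone by edgeR's test, each of them lower. AKR1B10, an aldo-keto reductase, had 24624 counts against 9039 and 6491 and stood at -2.08 (SE 0.36), AKR1C1 at -1.84 (SE 0.36) and PGD, of the pentose phosphate pathway, at -1.52 (SE 0.35). Of 35 hypoxia and glycolysis genes 24 were lower in both, with a median of -0.54, among them SLC2A1, the glucose transporter GLUT1 (-1.42, SE 0.37), and LDHA, lactate dehydrogenase (-1.13, SE 0.38). Of 32 cholesterol and fatty acid synthesis genes 29 were lower in both, with a median of -0.78, among them the desaturases FADS1 (-1.34, SE 0.33) and FADS2 (-1.57, SE 0.49), the elongase ELOVL6 (-1.83, SE 0.62) and INSIG1 (-1.22, SE 0.37). Camera with a preset correlation gave adjusted p = 3.33e-19 for the NRF2 list, 5.83e-06 for hypoxia and glycolysis and 1.57e-11 for lipid synthesis, and each had an adjusted p = 0.664 with an estimated correlation. The lipid synthesis median was -0.42 in library 1 and -1.23 in library 2, that of hypoxia and glycolysis -0.34 and -0.75, and that of NRF2 -0.86 and -1.18. How far these lie below 0 depends on the scaling. With library size alone the median of all genes was 0.467, against 0.039 in the main test. Random lists of the same expression had medians of -0.27 for NRF2, -0.23 for hypoxia and glycolysis and -0.21 for lipid synthesis, over both libraries. Camera with a preset correlation also called the NRF2, hypoxia and lipid lists lower when library 2 was set alone against scramble and library 1.

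Signalling genes ranked higher in the shKLF5 libraries. Camera with a preset correlation also called the MAPK and p53 lists higher, but not NF-kB, with library 2 set alone against scramble and library 1. Of 27 MAPK feedback, EGFR ligand and AP-1 genes 20 were higher by value in both and 1 was lower in both, with a median log2 fold change of 0.99, among them SPRY4 (2.21, SE 0.46) and DUSP6 (2.32, SE 0.53), inhibitors of the ERK pathway, and the AP-1 subunits FOSB (2.48, SE 0.62) and JUN (2.61, SE 0.70). Of 25 NF-kB and inflammatory genes 15 were higher in both and 1 lower in both, with a median of 0.98, among them TNFAIP3, a brake on NF-kB (2.18, SE 0.40), BIRC3, an inhibitor of apoptosis (2.76, SE 0.56), and LIF, a cytokine of the IL-6 family (1.94, SE 0.47). Of 24 p53 targets 16 were higher in both and 5 lower in both, with a median of 0.55. Among the higher ones were GDF15, BBC3 (2.67, SE 0.93), which encodes the death factor PUMA, and SESN2 (2.53, SE 0.91). In libraries 1 and 2 BBC3 stood at 1.31 and 3.26, and SESN2 at 0.82 and 3.28. GDF15 and SESN2 are also known to respond to other stresses. Camera with a preset correlation gave adjusted p = 1.35e-08 for the MAPK list and 8.45e-07 for NF-kB, both with an adjusted p = 0.664 with an estimated correlation, and 0.00377 for p53 targets, with an adjusted p = 0.682 with an estimated correlation. Adjusted over the list alone, edgeR's test passed 8 MAPK genes, 6 NF-kB genes and 1 p53 target, GDF15, all higher. The p53 median was 0.29 in library 1 and 0.68 in library 2, and its call was lost with no filter on low counts (camera adjusted p = 0.129).

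**Figure D3:**
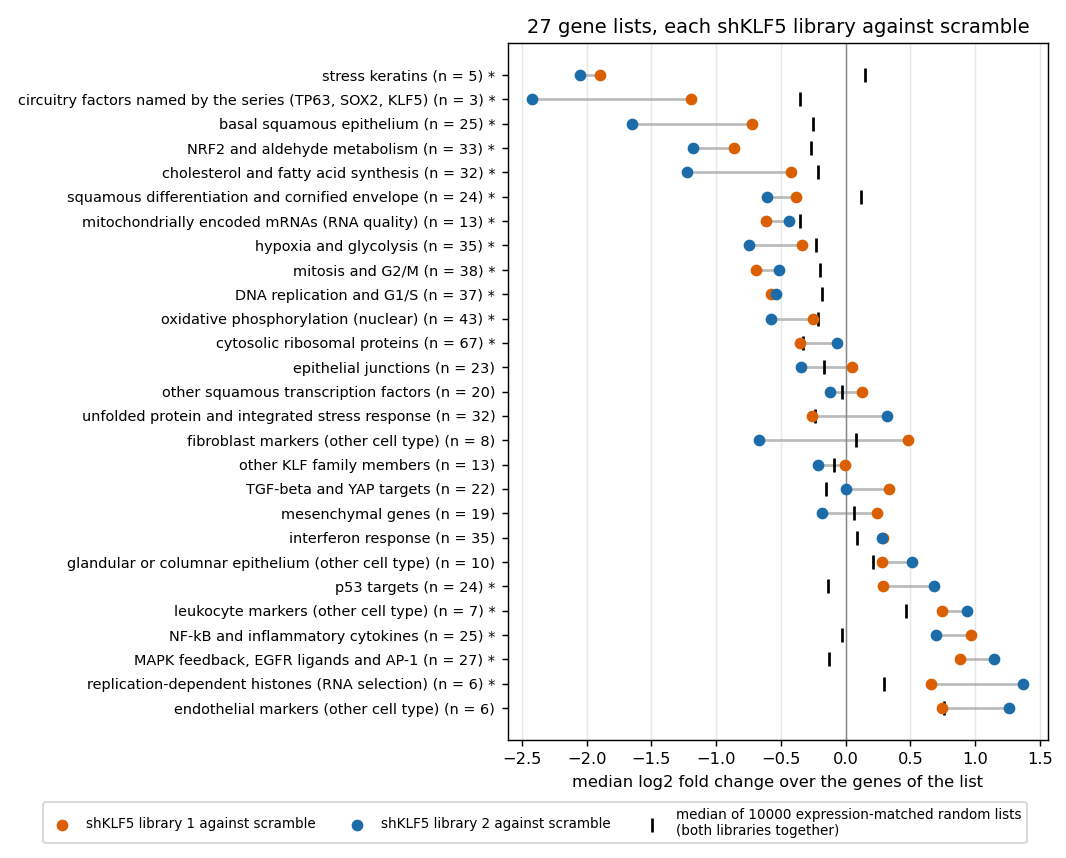
Median log2 fold change against scramble of 27 gene lists, 1 point for each shKLF5 library, with the number of genes tested in each list (n) and an asterisk at the 17 lists called by camera with a preset correlation. Black ticks give the median of expression-matched random lists, and the basal squamous list lies at -0.73 and -1.65 against a tick at -0.26.

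Some lists kept as measures of RNA quality and of other cell types were called too. Of 67 cytosolic ribosomal protein genes 52 were lower by value in both libraries (median -0.23), of 43 nuclear genes of oxidative phosphorylation 40 were (median -0.43), and of 13 mitochondrially encoded mRNAs 12 were (median -0.58). These medians have to be read beside -0.33, -0.21 and -0.35, the medians of random lists of the same expression, since abundant genes were lower in general. The ribosomal median turned positive under library size alone (0.198), but the median of all genes was 0.467 there, so it still lay below the typical gene. The ribosomal and mitochondrial medians turned positive under a correction for abundance. Examples are RPL3 at -0.68 (SE 0.34), ATP5F1C, a subunit of ATP synthase, at -0.87 (SE 0.38), and MT-CO1 at -0.70 (SE 0.62). Of 6 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 5 were higher in both, and HIST1H1E had 5, 25 and 84 counts. Of 7 leukocyte markers 5 were higher in both (median 0.71), all at low counts, such as ITGAM with 8, 72 and 108, where random lists of the same expression had a median of 0.46, against 0.30 for the histones. Camera with a preset correlation gave adjusted p = 0.00371 for ribosomal proteins, 5.49e-05 for oxidative phosphorylation, 0.00465 for mitochondrial mRNAs, 0.00715 for histones and 0.0159 for leukocyte markers, and in the same order the adjusted p was 0.829, 0.688, 0.688, 0.682 and 0.664 with an estimated correlation. The medians in libraries 1 and 2 were -0.35 and -0.07 for ribosomal proteins, -0.25 and -0.58 for oxidative phosphorylation and 0.66 and 1.37 for histones.

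The remaining 10 lists were not called by camera with a preset correlation. The same test called 18 lists when shKLF5 library 2 was taken as the lone library, and 13 with shKLF5 library 1 so taken, against 17 for scramble. Other members of the KLF family had a median log2 fold change of 0.07 over 13 genes, with KLF12 at -1.34 and KLF13 at -1.08 and KLF6 at 0.86 (camera adjusted p = 0.473). Other squamous transcription factors had a median of -0.01 over 20 genes (camera adjusted p = 0.723), with GRHL3 at -1.64 and FOSL1, with 813, 1696 and 7402 counts, at 2.09. Epithelial junction genes had a median of -0.14 over 23 (camera adjusted p = 0.356), of which 10 were lower in both and 9 higher in both, with CDH1, E-cadherin, at -1.47 and EPCAM at -1.16. Chosen after its values were seen, the tight junction gene CLDN1 stood at 1.54. Mesenchymal genes had a median of 0.17 over 19 (camera adjusted p = 0.723), where CDH11 stood at -2.69, TNC at 1.81 and VIM, at 39, 141 and 194 counts, at 1.69. For TGF-beta and YAP targets the median was 0.07 over 22 (camera adjusted p = 0.824), and 5 passed adjusted over the list alone by edgeR's test, F3 (-2.12) and AJUBA (-1.23) lower and ANKRD1, PMEPA1 (3.70) and INHBA higher. INHBA, chosen after its values were seen, had 19, 117 and 1182 counts, and ANKRD1 had 1409, 6662 and 8273. The unfolded protein and integrated stress response list had a median of 0.03 over 32 (camera adjusted p = 0.723), and -0.26 in library 1 against 0.32 in library 2, with PPP1R15A at 1495, 4994 and 23516 counts. Interferon response genes had a median of 0.22 over 35 (camera adjusted p = 0.283). Of markers of other cell types, fibroblast genes had a median of 0.05 over 8, endothelial genes 1.25 over 6 and glandular genes 0.29 over 10, with camera adjusted p = 0.723, 0.105 and 0.157. The fibroblast genes went both ways, and 3 passed adjusted over the list alone by edgeR's test, MFAP5 lower (4129, 1332 and 1021 counts) and PDGFRB (3, 39 and 35) and COL1A2 (1, 18 and 15) higher. Of the glandular genes 2 did, KRT7 (6, 56 and 80 counts) and MUC5B (0, 28 and 14), both higher. The sign of the median differed from that of the camera statistic for the other KLF, mesenchymal and fibroblast lists and for the other squamous factors, and the mean and median of the junction list differed in sign (0.09 and -0.14). GRHL2, CDH5, MUC5B and VIL1 had 0 counts in scramble, and with these genes at the bound that a floor of 3 counts gives, the medians of their lists were the same.

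The 2 shKLF5 libraries moved together more than in simulations with no effect and a shared control. There the scramble library was given the spread estimated from the shKLF5 libraries and no trend with abundance. Across 20629 genes the log2 fold changes of the 2 libraries against scramble had Pearson r = 0.686 and Spearman rho = 0.662, where 100 simulations with no effect and the same shared scramble library gave means of 0.517 and 0.491. The covariance was 0.594 against a simulated 0.296, a difference of 0.298, and 74.5% of genes had the same sign against 67.1%. Genes are not independent replicates, so no p-value is attached. With 1 scramble library the control could not be divided, and a scramble library more variable than simulated could give part or all of the excess. Among all genes 36.5% were lower in both libraries, 37.95% higher in both and 25.5% opposite. The fold changes followed abundance: below a log2 CPM of 0 the median was 0.49 in library 1 and 0.60 in library 2, and above 8 it was -0.42 and -0.54.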

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

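Tests of depth, of the groupings, of background reads, of the 2 parts of the gene lists and of the single scramble library were chosen after the results were seen, and those of GC content with length, of distinct RNA molecules and of the abundance trend over all called lists before. Transcripts matched to no gene of the annotation held 3.42% of estimated counts in shKLF5 library 1 and 3.4% in shKLF5 library 2, above the 3.05% of scramble, a signal outside the genes compared.

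With shKLF5 library 2 set against the other 2 libraries edgeR called 705 genes and camera 18 lists, against 0 genes and 17 lists for the real grouping and 0 genes and 13 lists with shKLF5 library 1 alone. The fits had prior degrees of freedom of 16.3 and 6.86 for library 2 and the real grouping, and the 705 include genes such as KRT14 (659, 37 and 10 counts) where library 1 also lay far from scramble, so the counts do not measure the distance of library 2 from library 1. The 3 groupings of 1 library against 2 are too few for a share under 0.05, with a real count of 0 and 705 as the highest other. Depth is argued against, since the totals of the 2 shKLF5 libraries had a ratio of 0.975, and so is bias from GC content and length, since after a correction for GC content and transcript length 1092 genes were called, 658 of them shared with the 705. The common dispersion measures spread within the pair of libraries in each fit. It was 0.08185 for scramble with shKLF5 library 1, 0.1085 for the 2 shKLF5 libraries and 0.2058 for scramble with shKLF5 library 2. By this measure library 1 lay closer to scramble than to library 2. With library 2 alone, camera also called, in the same direction, the lists called against scramble other than NF-kB, ribosomal proteins and mitochondrial mRNAs. Whether the libraries come from different hairpins or different cultures is not in the labels and stays open and untested.

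Genes of low abundance lay higher in both shKLF5 libraries than in scramble, with a median log2 fold change of 0.49 and 0.60 below a log2 CPM of 0. A scramble library with fewer distinct RNA molecules would keep the pooled level of such genes, but the pooled CPM of 21534 genes under 1 CPM was at least 1.87 times that of scramble in both. Reads from genomic DNA or another even background may contribute, since 358 olfactory receptor genes, which squamous cells are not known to use, had at least 2.01 times the CPM of scramble in both, on 205, 450 and 402 counts. The same would be seen if silent genes were transcribed more broadly, a biological explanation that these tables do not exclude. Genes with few counts in scramble, such as ITGAM, CDH5 and MUC5B, are read with that in mind.

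Of the 17 gene lists called by camera with a preset correlation, 13 were still called the same way after each library was corrected for its trend with abundance, between the bounds set for and against the trend. The trend is argued against as the whole cause for the 12 called squamous, growth, signalling and metabolic lists, since all 12 kept their call, though the circuit list, which holds KLF5 itself, is 1 of them and is set aside here. Of the 5 called ribosomal, respiratory, RNA quality and other-cell-type lists 1 was kept (histones), within the bound set for the trend. The trend may therefore account for some of these calls, but not for that of histones. Oxidative phosphorylation lost its call but kept its direction. Its median of -0.43 also lay below -0.21, the median of random lists of the same expression. With 1 scramble library, a peculiarity of that library cannot be told apart from an effect of the hairpins for any of these lists. An effect of KLF5 loss stays open as the biological explanation.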

How the results depend on the processing

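The abundance correction and the fit without mitochondrially encoded genes were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers, scramble having a single unnumbered library. The scramble library has no replicate, so no alternative tests its own spread. The count of 0 genes became 21 with edgeR's legacy fit, 118 with DESeq2 and 2 without mitochondrial genes, and stayed 0 in the 10 others. KLF5 was -2.96 with the legacy fit (adjusted p = 0.0149) and -2.996 with DESeq2 (adjusted p = 1.51e-06), and past the threshold only there. Over 13 settings, each library alone included, the log2 fold change ran from -3.08 to -2.25 for KLF5, -2.42 to -1.17 for TP63, -1.82 to -0.01 for SOX2 and -3.29 to -2.19 for ALDH3A1, whose adjusted p ran from 0.00128 to 0.685. Of 120 named genes other than KLF5, TP63 and SOX2, 39 passed with DESeq2 and 10 with the legacy fit. Library size alone shifted the median gene to 0.47 and limma on log2(TPM + 1) to 0.26, against 0.04 in the main test, so values there are read relative to that shift. In the ranges above, the values of each library alone used TMM scaling only. In TPM, SOX2 was higher in library 1 (113) than in scramble (81.5).

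Of the 17 called lists, 10 kept their call and direction in every other scaling, filter and count setting run for them, 7 settings each and 6 for stress keratins. With an estimated correlation the adjusted p of the called lists was 0.664, 0.682, 0.688 or 0.829, and with fry 0.344, 0.345, 0.361, 0.379, 0.532, 0.535 or 0.572, so none passed, and neither did the planted list of the simulation. Fry asks whether a list's genes move one way at all and not whether they differ from other genes, so its p is no test of the camera calls. Ribosomal proteins had camera adjusted p = 0.0765 with library size alone and 0.393 at a mean CPM of at least 5. With no filter, p53 targets and histones both had 0.129. At a mean CPM of at least 5, differentiation had 0.0687, mitochondrial mRNAs 0.068 and fibroblast markers were newly called lower (0.00355). With the abundance correction, oxidative phosphorylation had 0.0717, leukocyte markers 0.11, and the stress response list was newly called higher (0.0165). The cause was not tested for these. Camera's direction turned for other squamous factors (0.768), mesenchymal genes (0.991), the stress response (0.357) and fibroblast markers (0.472) with no filter, for mesenchymal genes with length-scaled TPM (0.953), for glandular markers at a mean CPM of at least 5 (0.911), and with the abundance correction for junctions (0.797), ribosomal proteins (0.292) and mitochondrial mRNAs (0.0677), none of them called there. Medians turned for ribosomal proteins, 0.198 with library size alone and 0.143 with the abundance correction, and for mitochondrial mRNAs, 0.295 with that correction, by construction since it raises abundant genes. MT-ATP8 (0.079), MT-ND4L (0.114), MT-ND1 (0.255) and MT-CO1 (0.255) turned there too, and ERG, at 12, 10 and 4 counts, stood at 0.045 with limma on log2(TPM + 1), the cause not tested.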

Other observations

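The test of HERV-H sequence and all other choices of genes in this part were made after the values were seen. Of 26 keratin genes tested, 14 were lower by value in both shKLF5 libraries, 8 were higher in both and 4 went opposite ways, and 11 were lower and 5 higher at an unadjusted p under 0.05 by edgeR's test. Beside KRT75, the higher ones included KRT80 with 203, 1062 and 1499 counts, KRT7, a keratin of simple epithelia, with 6, 56 and 80, and KRT78 with 1, 14 and 13, the last 2 at levels where background reads also count. Most TP63 counts lay in the transcripts that start at the internal promoter and encode the delta N forms of p63, with 8176 counts in scramble against 4716 and 1949. Those that start upstream had 204, 223 and 98 counts, so both classes were lower in library 2.

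Some genes lay farther from scramble in library 2 than in library 1, and no list of BMP targets was tested. ID1, ID2 and ID3, inhibitors of differentiation that BMP induces, had 227, 295 and 1099 counts in library 2 against 2034, 1993 and 5222 in library 1 and 2637, 1757 and 5702 in scramble. The stress genes DDIT3, ATF3 and TRIB3 had 4302, 9979 and 9775 counts in library 2 against 1073, 2305 and 2264 in library 1 and 559, 771 and 1910 in scramble. Over whole gene lists, the median difference of library 2 from library 1 was -1.23 on the log2 scale for the circuit, -0.87 for basal squamous genes, -0.71 for lipid synthesis and 0.63 for the stress response. It was -0.70 for mesenchymal genes, and control lists differed as well, by 0.61 for leukocyte markers, 0.61 for histones and -0.50 for fibroblast markers.

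A window of count ratios, set after the values were seen, held 10 genes that were lower in both shKLF5 libraries by a nearly constant ratio. Among them HHLA1 had 9576 counts in scramble against 2902 and 4103, and AP000547.3 had 5185 against 1633 and 2364. Transcripts of 8 of the 10 share words of 31 bases with another of the 10, and HHLA1 is named for a long terminal repeat of HERV-H, an endogenous retrovirus best known from pluripotent cells. A hypothesis is that RNA from HERV-H copies carried by these transcripts is lower, and several definitions of the genes to test were tried in turn, each after the values of the one before were seen. The 55 other tested genes that share such words with the 10 had medians of 0.12 in library 1 and 0.25 in library 2, and 9 of them lay at -1 or less in both. The 27 genes that share a word with ERVH-1, a noncoding gene of HERV-H origin already seen to be low (442, 159 and 228 counts), had medians of -0.16 and 0.03, and 7 of them lay at -1 or less in both, but 4 of the 27 belong to the 10 genes that raised the question. With a mean CPM of at least 5 there were 15 of these, and 6 lay at -1 or less in both, where 2.17% of all genes at that abundance did, but the same 4 are among the 6. No random lists were drawn for the 55 and the 27. With those left out, 2 of 11 did, where random lists matched on expression had a median of 0 and a 99th percentile of 2, and the medians of the 11 were -0.03 and 0.06. The test of lower RNA from HERV-H copies therefore leaves the hypothesis undecided (value 2). Shared sequence also lets kallisto move counts between these genes, so they are not independent.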
